A study of Mus musculus with 16 samples.

How the data were processed

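RNA was measured in 16 libraries of circulating neutrophils with low surface CD62L, sorted by flow cytometry from the blood of C57BL/6 mice. Per the labels, the libraries form 4 groups of 4: young (3 months) and aged (18 months) mice, each untreated (basal) or 24 h after middle cerebral artery occlusion (MCAo), an experimental ischaemic stroke in which a brain artery is blocked. Total RNA was extracted from sorted cells and amplified with the SMART-Seq v4 kit over 17 PCR cycles, per the labels' protocols. This kit does not mark the strand, so reads of a gene and of an antisense partner cannot be told apart.

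The values are raw read counts per gene symbol, deposited by the authors as 1 table without normalisation. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.3a and featureCounts, and the genome build GRCm38. The roles of these tools, the gene annotation and the strand setting are not given in the sources used here. Of 53278 symbols, 49721 matched a gene name in the GENCODE M21 annotation of GRCm38, as did 13256 of the 13613 symbols tested, and coordinates are those of the matched gene. Counts of near-identical genes can be split by the counting and are uncertain: the class I gene H2-Q6, Ifit3 and Ifit3b, the globins Hba-a1 and Hbb-bs, the histone gene Hist2h4, Skint3, Chil3, the interferon gene Ifi27l2a, and ribosomal protein genes, which have many pseudogenes. Exons of Mmp19 overlap those of other genes over 22.3% of their length and those of Itgam over 68.7%, so their counts may hold reads of a neighbour.

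Libraries of a group differed by more than counting noise (chi-square per gene 46.3 to 202 over 24 pairs). Each was counted as a sample, as the labels list them. Aged basal replicates 3 and 4 have near-identical sample names, whose meaning is not given in the sources used here. They may be preparations of 1 sample, in which case that group has n = 3, and their chi-square of 48.6 lies within the range of the other pairs and does not settle it. Libraries are also named by group and number (young MCAo 1), and those joined by "or" were left out 1 at a time. Nothing in the labels says that libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical. PCR copies cannot be told from separate molecules here, so counting intervals and floors cover counting error only.

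Differences were tested on the counts with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (13613 genes), scaled by TMM, and fitted with a robust quasi-likelihood model of 4 group means over all 16 libraries, with 12 residual degrees of freedom and no replicate block. Contrasts were aged against young at baseline, aged against young after MCAo, MCAo against basal at each age, and the interaction (the MCAo change in aged minus that in young mice). Adjusted p-values are Benjamini-Hochberg values of the edgeR quasi-likelihood test, 2-sided, with a threshold of 0.05. CPM values are counts relative to library size, scaled by TMM. Lists of genes (granule, maturation, metabolic, signalling and stress programmes, and markers of other blood cells) were fixed with the rule below and tested with camera (limma 3.58.1), with a preset correlation between genes of 0.01. They were also tested with a correlation estimated per list and with fry, a test of whether the genes of a list move on balance one way. Adjusted p-values of lists cover the 33 lists with at least 3 tested genes. Correlations across genes carry no p-value, since genes are not replicates.

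The genes named were set by a rule fixed before the data were examined: per comparison the 10 largest rises and 10 largest falls by log2 fold change that passed the threshold, with a mean of at least 5 CPM and no overlap between the groups, and the 10 largest interaction values. To these come up to 4 members of each list with the smallest adjusted p, and Cxcr2, Cxcr4, Ly6g, Itgam, S100a8, Il1b, Mpo, Ltf and Camp; a further gene set in advance is not reported here. Unnamed gene models were counted but not named.

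The test was run on simulated counts of the same libraries with genes changed by known folds. It recovered 19.6% of 2-fold and 51.6% of 4-fold changes between the basal groups, 11.2% and 57.9% between the MCAo groups, 14.4% and 50.0% for MCAo in young, 13.7% and 46.3% for MCAo in aged, and 4.21% and 37.1% for the interaction. Alternatives tried were DESeq2 size factors, no filter, a filter at a mean of 5 CPM, the DESeq2 1.42.0 Wald test, limma-voom with sample weights, only the 8 libraries compared, a replicate block, and each library left out in turn; leaving out aged MCAo replicates 2 and 4 together was added after the data were seen. Listed genes too low to be tested were left out: 7 of 14 azurophil granule and progenitor genes (Mpo, Elane and Ctsg among them), 6 of 13 mitochondrially encoded protein genes, 11 of 30 cell cycle genes, 11 of 15 T cell, 5 of 8 plasma cell, 5 of 9 eosinophil and 4 of 9 dendritic cell markers, and up to 5 of any other tested list. NK cell and basophil markers had no tested gene and endothelial markers had 2, so these lists were not tested. Among the mitochondrially encoded genes mt-Nd4l, mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8 had 0 counts in every library, so the counting of this genome is uncertain.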

Results

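Transcripts of sorted CD62L-low blood neutrophils were counted in 4 untreated young, 4 untreated aged, 4 young MCAo and 4 aged MCAo samples. Total counts ranged from 9709452 to 30958858 in young basal, 16729496 to 29833653 in aged basal, 12697040 to 22431301 in young MCAo and 13689589 to 19175693 in aged MCAo libraries. Between 15431 and 18829 genes were detected per library, except in aged basal replicate 4 with 25350. The first principal component held 24.1% of the variance and separated the basal libraries, at -73.2 to -34.7, from the MCAo libraries, at 18.5 to 113. No sham-operated group was analysed here, so a difference between MCAo and untreated mice covers surgery and anaesthesia as well as the occlusion.

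The comparison of untreated aged and young mice asked what age changes in these cells before stroke. Hjurp, a chaperone that loads the centromeric histone CENP-A (chromosome 1, 88262471 to 88277633), was the single gene that passed: it rose from 16.1 ± 4.07 CPM in young to 41.6 ± 6.35 CPM in aged mice (SD, n = 4; log2 1.37, SE 0.21, adjusted p = 0.0429 by edgeR), with all 4 aged above all 4 young libraries. Genes set in advance that did not pass were Cxcr2 (log2 -0.16), Cxcr4 (0.24), Ly6g (-0.39), Itgam (0.01), S100a8 (0.29), Il1b (0.09) and the granule genes Ltf (-3.14, SE 1.80) and Camp (-2.11, SE 1.39). At an unadjusted p under 0.05 edgeR gave 1165 genes, while at an adjusted p under 0.05 DESeq2 called 157 and limma-voom 0. The edgeR count was 5 without young basal 1 and 3 without young basal 2 or 4. It was 1 without aged basal 3 or aged MCAo 2, and 0 without any other single library. Hjurp was not called on leaving out any library but young basal 1 or aged MCAo 2 (adjusted p 0.0507 to 0.124). Hjurp was not called with DESeq2 size factors (adjusted p = 0.0586), by limma-voom (adjusted p = 0.173), without aged MCAo 2 and 4 (adjusted p = 0.0539) or from the 8 libraries alone (adjusted p = 0.248).

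Over all genes tested, no member of any list passed. Of 42 interferon-stimulated genes, 0 were lower, or 1 adjusted over the list alone (camera adjusted p = 1.96e-12, adjusted p = 0.865 with an estimated correlation), with a median log2 of -0.54 in aged against young mice. The 75 cytosolic ribosomal protein genes had a median of -0.24 (camera adjusted p = 9.29e-09, adjusted p = 0.898 with an estimated correlation), the 12 MHC class II genes one of 0.66 (camera adjusted p = 0.0118, adjusted p = 0.378 with an estimated correlation) and the 12 platelet markers one of 0.70 (camera adjusted p = 0.00105, adjusted p = 0.873 with an estimated correlation), with no member of these lists passing over the list alone. Class II genes are abundant in B cells, whose markers had a median of 0.15 (camera adjusted p = 0.472). The mean log2 CPM of the B cell markers was 0.52 to 1.90 in young and 2.18 to 2.29 in aged libraries, that of class II genes 0.56 to 2.02 and 2.21 to 2.93, and that of monocyte and macrophage markers 1.58 to 2.47 and 2.43 to 3.83. The latter markers had a median of 0.78 (camera adjusted p = 0.0624). Of the lists, camera with the preset correlation called 8 of 33, 0 with an estimated correlation, and fry called 0. As many lists were called in 2 of 35 splits of the same libraries, the real one included. Without young basal 2 or 4 or aged basal 4 the camera count was 4, 3 or 5. MHC class II presentation genes were not called without young basal 2 or 4 (adjusted p 0.0513 to 0.0798).

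In young mice the change 24 h after MCAo was broad, with 637 genes higher and 571 lower than in untreated young mice. Chil3, a chitinase-like protein of neutrophil granules (chromosome 3, 106147554 to 106167564), rose from 18.6 ± 14.7 to 1532 ± 1351 CPM (SD, n = 4; log2 6.37, SE 0.76, adjusted p = 6.66e-05). Fkbp5, a co-chaperone induced by glucocorticoids (chromosome 17, 28399094 to 28517527), rose from 5.36 ± 1.61 to 106 ± 38.2 CPM (log2 4.29, SE 0.33, adjusted p = 8.19e-07). Rptor, a subunit of the growth-regulating kinase complex mTORC1 (chromosome 11, 119602905 to 119899576), rose from 1.04 ± 0.662 to 64.7 ± 36.9 CPM (log2 5.86, SE 0.73, adjusted p = 9.57e-05). Rtp4, an interferon-induced gene (chromosome 16, 23520291 to 23614222), fell from 644 ± 130.1 to 105 ± 11.5 CPM (log2 -2.62, SE 0.39, adjusted p = 4.53e-04), and Il1b, which encodes interleukin-1 beta (chromosome 2, 129364570 to 129371139), from 11280.4 ± 1578 to 4734 ± 1363 CPM (log2 -1.25, SE 0.26, adjusted p = 0.00630). Chil3 (log2 7.01 without young basal 2 and 5.55 without young MCAo 3) moved by over 1.5 times in fold.

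Further large rises were those of Lipg (log2 5.90), the endothelial lipase gene, Dpep2 (5.01), a dipeptidase that cleaves leukotriene D, Lrrc75b (4.97), Nos2 (4.63), the inducible nitric oxide synthase, Cd38 (4.60), an ectoenzyme that consumes NAD, and Serpinb10 (4.10), with adjusted p from 7.21e-05 to 0.0132. Fam169b had 1 count over the 4 young basal libraries, and its ratio was 265 with a 95% counting interval of 47.2 to 10526. Further large falls were those of the chemokine Cxcl10 (-4.89), the transcription factor Egr2 (-4.22), the antiviral tether Bst2 (-3.12) and Ifit2 (-2.98), with adjusted p from 2.65e-04 to 0.0106. Ifit3 (-2.92), Ifit3b (-2.82), Ifi27l2a (-2.79), the histone gene Hist2h4 (-2.74) and the class I gene H2-Q6 (-2.74) also fell, with adjusted p from 2.41e-04 to 0.0260, but have close copies in the genome, so their counts are uncertain. By the naming rule the 4 libraries of a group lay apart from the other 4 in these largest changes. Ly6g (2.06, adjusted p = 0.00174) and Itgam (0.64, adjusted p = 0.0115), both markers of neutrophils, rose, while Cxcr2 (-0.12), Cxcr4 (-0.66), S100a8 (0.50), Ltf (-1.61) and Camp (-1.44) did not pass. H2-Q6 was not called without young basal 2 or young MCAo 2, 3 or 4 (adjusted p 0.0582 to 0.0843). Lrrc75b and Serpinb10 were not called from the 8 libraries alone (adjusted p 0.0509 to 0.0895). Cd38 was not called by limma-voom (adjusted p = 0.196). Lipg (1 count left in the lower group without young basal 4 and log2 5.12 without young MCAo 4), Dpep2 (6.11 without young basal 2), Lrrc75b (0 counts left in the lower group without young basal 1), Nos2 (1 count left in the lower group without young basal 2), Cd38 (3.87 without young MCAo 4), Serpinb10 (5.86 without young basal 1) and Egr2 (-4.87 without young MCAo 1) moved by over 1.5 times in fold.

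Of 42 interferon-stimulated genes, 24 fell, or 28 adjusted over the list alone (camera adjusted p = 1.87e-27, adjusted p = 0.0950 with an estimated correlation), with Oasl1 at log2 -2.56. Of 17 MHC class I presentation genes, 12 fell, or 12 adjusted over the list alone (camera adjusted p = 4.74e-11, adjusted p = 0.0566 with an estimated correlation). These included the peptide transporter Tap1 (-1.04) and the immunoproteasome subunit Psmb9 (-1.07). Of 75 cytosolic ribosomal protein genes, 47 fell, or 69 adjusted over the list alone (camera adjusted p = 2.87e-36, adjusted p = 0.10 with an estimated correlation), with Rps19 at -1.36; the list median was -0.86, and that of genes outside it matched on length and level -0.37. Of 74 nuclear oxidative phosphorylation genes, 18 fell, or 30 adjusted over the list alone (camera adjusted p = 9.94e-14, adjusted p = 0.210 with an estimated correlation). These included Atp5e (-1.56) and Ndufs7 (-1.17). Of 19 immediate-early and heat shock genes, 7 fell, or 9 adjusted over the list alone (camera adjusted p = 1.45e-08, adjusted p = 0.0969 with an estimated correlation). These included Atf3 (-2.21). Of 30 NF-kappaB target and cytokine genes, 1 rose and 8 fell, or 3 and 10 adjusted over the list alone (camera adjusted p = 4.38e-04, adjusted p = 0.214 with an estimated correlation). Markers of B cells, which a gate for neutrophils would remove, moved with these groups: their summed level, with Cd74, went from 487 to 136 CPM while that of the ribosomal protein genes went from 13044 to 7651 CPM. Of 12 B cell markers, 4 fell, or 7 adjusted over the list alone (camera adjusted p = 2.31e-06, adjusted p = 0.0566 with an estimated correlation). Ighm was at -1.81. Of 12 MHC class II presentation genes, 3 fell, or 5 adjusted over the list alone (camera adjusted p = 0.0213, adjusted p = 0.156 with an estimated correlation), with Cd74, which B cells also express, at -1.83. Of 10 erythroid markers, 2 fell, or 4 adjusted over the list alone (camera adjusted p = 9.05e-04, adjusted p = 0.399 with an estimated correlation). Hba-a1 was at -1.46. MHC class II presentation genes were not called without young basal 3 (adjusted p = 0.0811). Hba-a1 was not called without young basal 1 or 3, aged basal 1 or 4, young MCAo 1, 2 or 4 or aged MCAo 4 (adjusted p 0.0521 to 0.148).

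Of 17 specific granule genes, 5 rose, or 7 adjusted over the list alone (camera adjusted p = 8.29e-06, adjusted p = 0.206 with an estimated correlation). These included Lcn2 (log2 2.38), the iron-sequestering lipocalin, Olfm4 (3.13) and Cd177 (2.06). Of 14 gelatinase granule and secretory vesicle genes, 5 rose, or 6 adjusted over the list alone (camera adjusted p = 5.73e-04, adjusted p = 0.210 with an estimated correlation). These included the collagenase Mmp8 (1.67), Mmp25 (1.43) and the formyl peptide receptor Fpr2 (1.13). Of 25 mature neutrophil genes, 5 rose and 2 fell, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.614), with Retnlg (1.95) and the decoy receptor Il1r2 (1.77) among the rises. Of 15 glucocorticoid-induced genes, 4 rose, or 7 adjusted over the list alone (camera adjusted p = 2.15e-05, adjusted p = 0.0969 with an estimated correlation), Fkbp5 among them. In all, 1208 of 13613 genes passed the edgeR test, 772 without young basal replicate 1, 699 without young MCAo replicate 3, 627 without young MCAo replicate 4 and 1910 by DESeq2. The split was 682 higher and 701 lower with a filter at a mean of 5 CPM, 757 and 782 by limma-voom and 758 and 793 without aged MCAo 2 and 4. Of the lists, camera with the preset correlation called 17 of 33, 0 with an estimated correlation, and fry called 14. As many lists were called in 1 of 35 splits of the same libraries, the real one included.

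In aged mice the same comparison gave 1199 higher and 1281 lower genes. The split was 1301 higher and 1179 lower with DESeq2 size factors, 1629 and 1507 by DESeq2, 776 and 759 without aged MCAo 2 and 4, 1316 and 1279 without young basal 2, 1266 and 1223 without young basal 3 and 1204 and 1192 without young MCAo 2. Cd38 (chromosome 5, 43868553 to 43912375) rose from 0.209 ± 0.211 to 156 ± 112 CPM (SD, n = 4; log2 9.35, SE 0.88, adjusted p = 1.52e-06), and Prok2, a secreted prokineticin (chromosome 6, 99711299 to 99726392), from 0.668 ± 0.664 to 158 ± 32.4 CPM (log2 7.84, SE 0.62, adjusted p = 2.09e-07). Ngp, a neutrophil granule protein (chromosome 9, 110419747 to 110423012), rose from 27.5 ± 10.9 to 4350.3 ± 6679 CPM (log2 7.30, SE 1.13, adjusted p = 2.21e-04), with 14268 CPM in aged MCAo replicate 4 and 318 to 2379 CPM in the other libraries of the group. Egr1 (log2 -4.94, SE 0.76, adjusted p = 1.83e-04) and Fosb (-4.51, SE 0.48, adjusted p = 4.05e-06), immediate-early transcription factors, fell. Il1b fell from 12020.5 ± 2599 to 2872 ± 1125 CPM (log2 -2.07, SE 0.27, adjusted p = 3.06e-05). Cd38 (log2 8.75 without aged MCAo 4), Prok2 (8.86 without aged basal 1), Ngp (5.24 without aged MCAo 4) and Egr1 (-5.62 without aged MCAo 4) moved by over 1.5 times in fold.

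**Figure D1:**
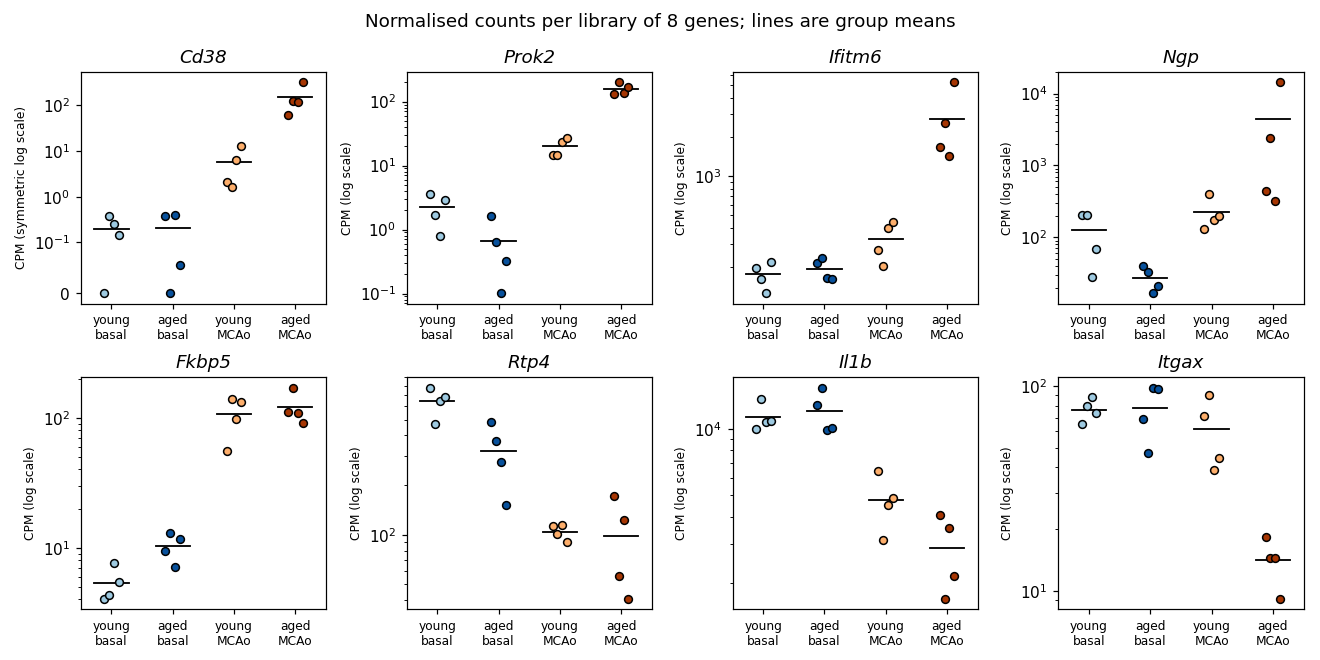
Normalised counts (CPM, on a log or symmetric log scale) of 8 genes in each of the 16 libraries, where points are libraries and lines are group means. Mean Cd38 after MCAo was 5.68 CPM in young and 156 CPM in aged mice, and mean Il1b was 4734 and 2872 CPM.

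Further large rises were Mmp19 (log2 10.29), a matrix metalloproteinase whose exons partly overlap another gene, Lipg (8.47), Chil3 (8.47), the neutrophil-attracting chemokine Cxcl3 (7.55), Ggt1 (6.90), which cleaves glutathione, Nos2 (6.47) and the prion protein gene Prnp (6.17), with adjusted p from 2.49e-06 to 7.94e-04. Further large falls were Abcg3 (-4.40), Ptgs2 (-4.28), the inducible cyclooxygenase, Hgh1 (-4.07), Cxcl10 (-3.99), Igf2bp2 (-3.92), Kank3 (-3.86), Calhm2 (-3.80) and the ribonuclease Rnase6 (-3.73), with adjusted p from 1.14e-05 to 0.00711. Ly6g (3.85, adjusted p = 3.17e-06), Itgam (1.02, adjusted p = 1.1e-04) and S100a8 (1.04, adjusted p = 0.0481) rose. Cxcr4, the receptor that retains neutrophils in bone marrow, fell (-1.56, adjusted p = 8.69e-05), while Cxcr2 (0.43), Ltf (5.03, SE 1.95) and Camp (4.06, SE 1.49) did not pass. S100a8 was not called without young basal 1 or 3, aged basal 1, 3 or 4, young MCAo 2 or aged MCAo 1, 2 or 4 (adjusted p 0.0502 to 0.132). Cxcl10 and S100a8 were not called without aged MCAo 2 and 4 (adjusted p 0.0674 to 0.395). S100a8 was not called by limma-voom (adjusted p = 0.223). Mmp19 (log2 11.06 without aged basal 2), Lipg (2 counts left in the lower group without aged basal 4), Nos2 (7.95 without aged basal 4), Prnp (7.33 without aged basal 2), Abcg3 (-5.05 without aged MCAo 1), Hgh1 (0 counts left in the lower group without aged MCAo 1), Cxcl10 (-5.84 without aged MCAo 1), Igf2bp2 (-5.19 without aged MCAo 3) and Kank3 (-5.21 without aged MCAo 3) moved by over 1.5 times in fold.

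Of 17 specific granule genes, 14 rose and 1 fell, or 16 and 1 adjusted over the list alone (camera adjusted p = 6.97e-21, adjusted p = 0.0220 with an estimated correlation), with Ifitm6 (log2 3.82), Cd177 (3.63) and Lcn2 (3.27) among the rises. The mean log2 CPM of this list was 10.57 in aged MCAo replicate 4 and 8.76 to 9.04 in the others of the group. Of 14 gelatinase granule and secretory vesicle genes, 9 rose, or 9 adjusted over the list alone (camera adjusted p = 4.9e-10, adjusted p = 0.0422 with an estimated correlation), as Mmp8 (2.87), Fpr2 (1.80) and Mmp25 (1.76); its mean log2 CPM was 9.50 in aged MCAo replicate 2 and 9.91 to 9.93 in the others. Of 25 mature neutrophil genes, 8 rose and 4 fell, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.00587, adjusted p = 0.405 with an estimated correlation). Il1r2 was at 3.34 and Retnlg at 2.82. Of 15 glucocorticoid-induced genes, 6 rose, or 7 adjusted over the list alone (camera adjusted p = 4.57e-04, adjusted p = 0.144 with an estimated correlation). Fkbp5 was at 3.56. Of 12 genes raised in CXCR4-high neutrophils that have aged in the circulation, 4 rose and 5 fell, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.960), with Tlr4 (1.85) among the rises and the integrin Itgax (-2.46) and Cd101 (-2.19) among the falls; the median of 0.38 and the mean of -0.04 differed in sign, and camera pointed down without a call.

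Of 75 cytosolic ribosomal protein genes, 44 fell, or 60 adjusted over the list alone (camera adjusted p = 4.82e-18, adjusted p = 0.229 with an estimated correlation), as Rps15 (log2 -1.41); the list median was -0.85 and that of matched genes outside it -0.22. Of 42 interferon-stimulated genes, 3 rose and 16 fell, or 4 and 18 adjusted over the list alone (camera adjusted p = 1.88e-04, adjusted p = 0.444 with an estimated correlation). Bst2 was at -2.60. Of 17 MHC class I presentation genes, 8 fell, or 9 adjusted over the list alone (camera adjusted p = 3.91e-06, adjusted p = 0.109 with an estimated correlation). Psmb9 was at -1.14 and Tap1 at -1.07. Of 74 nuclear oxidative phosphorylation genes, 1 rose and 17 fell, or 1 and 17 adjusted over the list alone (camera adjusted p = 3.76e-05, adjusted p = 0.451 with an estimated correlation). Atp5e was at -1.72 and Ndufs7 at -1.34. Of 19 immediate-early and heat shock genes, 1 rose and 10 fell, or 3 and 11 adjusted over the list alone (camera adjusted p = 5.84e-08, adjusted p = 0.10 with an estimated correlation). Atf3 was at -3.66. Of 30 NF-kappaB target and cytokine genes, 6 rose and 14 fell, or 6 and 17 adjusted over the list alone (camera adjusted p = 0.00124, adjusted p = 0.281 with an estimated correlation), Ptgs2 among the falls. Beside these groups, B cell markers and Cd74 summed to 483 CPM before and 44.2 CPM after MCAo, and ribosomal protein genes to 10882 and 6711 CPM. Of 12 B cell markers, 9 fell, or 10 adjusted over the list alone (camera adjusted p = 1.44e-08, adjusted p = 0.0102 with an estimated correlation). Ighm was at -3.63. Of 12 MHC class II presentation genes, 3 fell, or 4 adjusted over the list alone (camera adjusted p = 0.00101, adjusted p = 0.0721 with an estimated correlation). Cd74 was at -2.57. Of 10 erythroid markers, 8 fell, or 9 adjusted over the list alone (camera adjusted p = 2.46e-07, adjusted p = 0.221 with an estimated correlation). Hba-a1 was at -2.39 and Hbb-bs at -2.53. Of 4 eosinophil markers, 3 fell, or 3 adjusted over the list alone (camera adjusted p = 0.0159, adjusted p = 0.221 with an estimated correlation). Siglecf was at -1.40. Siglecf was not called without aged basal 3 or 4 or aged MCAo 4 (adjusted p 0.0511 to 0.0707). Interferon-stimulated genes and Siglecf were not called without aged MCAo 2 and 4 (adjusted p 0.0539 to 0.124).

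**Figure D2:**
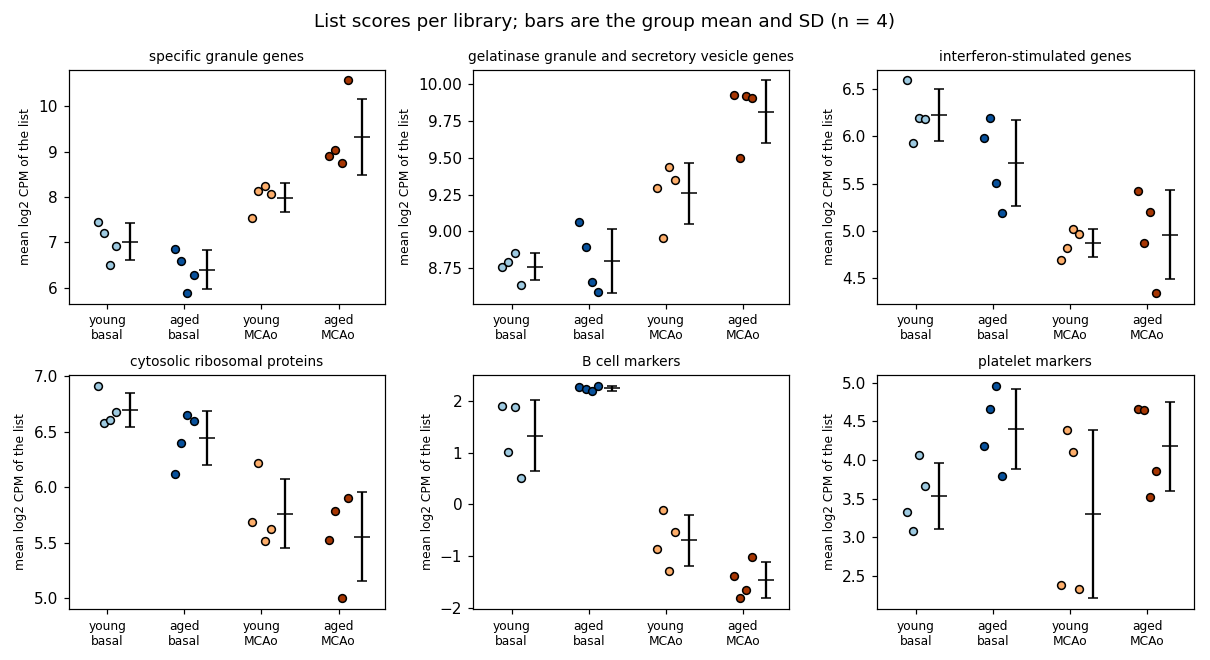
Mean log2 CPM of 6 gene lists in each of the 16 libraries, where points are libraries and bars are the group mean and SD (n = 4). The B cell score changed by -2.02 in young and -3.70 in aged mice after MCAo, and the platelet score by -0.23 and -0.22.

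In aged mice 2480 of 13613 genes passed the edgeR test, and 1535 without aged MCAo 2 and 4, chosen after seeing the data. Of the lists, camera with the preset correlation called 17 of 33, 3 with an estimated correlation, and fry called 24. As many lists were called in 3 of 35 splits of the same libraries, the real one included. Most genes went the same way at both ages: 1147 of the 1208 genes called in young mice (95%) had the same sign in aged mice. Of the genes called at both ages, 426 rose in both, 416 fell in both and 2 went opposite ways, where independent lists would share 56.1 rises and 53.7 falls. Across 13613 genes the log2 changes at the 2 ages had a Pearson r of 0.430 and a Spearman rho of 0.508, and an r of 0.742 over genes of at least 5 CPM. The age differences before and after MCAo had an r of 0.0286 and a rho of 0.0349. Neither pair of comparisons shares a library.

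After MCAo, aged and young mice differed in 182 genes, 97 higher and 85 lower in aged mice. Ifitm6, of the interferon-induced transmembrane family (chromosome 7, 141015699 to 141017924), was at 328 ± 112 CPM in young and 2732 ± 1748 CPM in aged mice (SD, n = 4; log2 3.06, SE 0.36, adjusted p = 3.22e-04). Cd38 was at 5.68 ± 5.11 and 156 ± 112 CPM (log2 4.81, SE 0.68, adjusted p = 0.00136), Cxcl3 (chromosome 5, 90786103 to 90789600) at 4.81 ± 2.47 and 103 ± 69.5 CPM (log2 4.44, SE 0.67, adjusted p = 0.00257), and Prok2 at 19.9 ± 6.18 and 158 ± 32.4 CPM (log2 3.00, SE 0.48, adjusted p = 0.00319). Itgax, the integrin CD11c (chromosome 7, 128129547 to 128150657), was lower in aged mice, at 14.1 ± 3.78 against 61.4 ± 24.1 CPM (log2 -2.12, SE 0.29, adjusted p = 0.00136). So was Anxa6, a membrane-binding annexin (chromosome 11, 54979108 to 55033445), at 39.0 ± 13.5 against 198 ± 46.8 CPM (log2 -2.34, SE 0.26, adjusted p = 2.22e-04). Cxcl3 was not called without aged MCAo 2 and 4 (adjusted p = 0.0525). Cd38 (log2 5.54 without young MCAo 4 and 4.19 without aged MCAo 4) moved by over 1.5 times in fold.

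Also higher in aged mice were Lipg (log2 4.19), H2-Q6 (3.59), the secretory kinase Fam20c (3.46), Ggt1 (3.29), Fam169b (3.08) and Serpinb1a (2.76), an inhibitor of neutrophil serine proteases, with adjusted p from 0.00257 to 0.0385. Lower in aged mice were Calhm2 (-3.33), Fosb (-2.54), the nucleosome assembly protein Nap1l1 (-2.43), Skint3 (-2.42), Amz1 (-2.24), Svip (-2.20), Abcg3 (-2.16) and Plekhm3 (-2.11), with adjusted p from 2.22e-04 to 0.0400. Cxcr2 (0.39), Cxcr4 (-0.66), Ly6g (1.40), Itgam (0.39), S100a8 (0.82), Il1b (-0.72), Ltf (3.50, SE 1.81) and Camp (3.39, SE 1.44) did not pass. H2-Q6 was not called without young MCAo 1, 2, 3 or 4 or aged MCAo 2 (adjusted p 0.0581 to 0.0839). Fam20c was not called without young MCAo 1, 3 or 4 or aged MCAo 4 (adjusted p 0.0503 to 0.0851). Ggt1 was not called without young MCAo 1 (adjusted p = 0.0545). Fam169b was not called on leaving out any library but young basal 2 or 4 or aged basal 1, 2, 3 or 4 (adjusted p 0.0502 to 0.160). Skint3 was not called on leaving out any library but young basal 2 or 4, aged basal 4 or aged MCAo 1 or 3 (adjusted p 0.0505 to 0.158). Amz1 was not called without young MCAo 1 or aged MCAo 4 (adjusted p 0.0545 to 0.0644). Svip was not called without young MCAo 1 or 4 or aged MCAo 4 (adjusted p 0.0590 to 0.0791). Abcg3 was not called without young MCAo 1, 2, 3 or 4 or aged MCAo 3 or 4 (adjusted p 0.0524 to 0.136). Lipg, H2-Q6, Fam20c, Ggt1, Fam169b, Fosb, Skint3, Amz1, Svip and Abcg3 were not called without aged MCAo 2 and 4 (adjusted p 0.0525 to 0.382). H2-Q6 and Fosb were not called by limma-voom (adjusted p 0.0716 to 0.102). H2-Q6, Skint3, Svip and Abcg3 were not called from the 8 libraries alone (adjusted p 0.0537 to 0.121). Lipg (log2 4.97 without young MCAo 4), H2-Q6 (1.84 without aged MCAo 2), Fam20c (2.73 without aged MCAo 4), Svip (-2.83 without aged MCAo 1) and Abcg3 (-2.81 without aged MCAo 1) moved by over 1.5 times in fold.

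Of 17 specific granule genes, 7 were higher, or 13 adjusted over the list alone (camera adjusted p = 1.67e-20, adjusted p = 0.0457 with an estimated correlation). These included Dstn (log2 1.43), which severs actin filaments, and Ltb4r1 (1.50), a leukotriene B receptor, neither of them itself a granule protein. The list's mean log2 CPM was 10.57 in aged MCAo 4 and 8.76 to 9.04 in the others of the group. Of 14 gelatinase granule and secretory vesicle genes, 5 were higher, or 8 adjusted over the list alone (camera adjusted p = 2.35e-10, adjusted p = 0.0570 with an estimated correlation). These included Mmp8 (1.41) and Fpr2 (0.93). This list's mean log2 CPM was 9.50 in aged MCAo 2 and 9.91 to 9.93 in the others. Of 21 glycolysis genes, 5 were higher and 0 lower, or 13 and 1 adjusted over the list alone (camera adjusted p = 3.25e-10, adjusted p = 0.0624 with an estimated correlation). These included Gapdh (0.95). Of 12 genes raised in CXCR4-high neutrophils, 1 was higher and 3 lower, or 4 and 5 adjusted over the list alone (camera adjusted p = 0.226), the lower ones being Itgax, the integrin Itga4 (-1.37) and Cd101 (-1.43); the median of 0.02 and the mean of -0.28 differed in sign. Of 7 azurophil granule and progenitor genes, 0 were higher and 1 lower, or 1 and 4 adjusted over the list alone (camera adjusted p = 0.00296, adjusted p = 0.0624 with an estimated correlation), the lower gene being Clec12a (-1.81), an inhibitory lectin receptor, while 7 more of this list, Mpo and Elane among them, were too low to be tested. Beside these groups, of 12 B cell markers, 0 were higher and 2 lower, or 1 and 3 adjusted over the list alone (camera adjusted p = 0.00442, adjusted p = 0.104 with an estimated correlation). Ighm was at -1.92. Of 10 erythroid markers, 0 were lower, or 8 adjusted over the list alone (camera adjusted p = 1.53e-08, adjusted p = 0.141 with an estimated correlation). Eosinophil markers had a median of -2.38 (camera adjusted p = 0.00955, adjusted p = 0.141 with an estimated correlation), at a mean log2 CPM of -0.43 in aged MCAo 2 and 0.85 to 0.98 in the others, and platelet markers one of 0.55 (camera adjusted p = 3.93e-04, adjusted p = 0.344 with an estimated correlation). Mmp8 was not called without young MCAo 1, 2 or 4 or aged MCAo 4 (adjusted p 0.0517 to 0.0861). Fpr2 was not called without young MCAo 1, 2, 3 or 4 or aged MCAo 2 or 4 (adjusted p 0.0554 to 0.106). Gapdh was not called without young MCAo 1, 2 or 4 or aged MCAo 3 or 4 (adjusted p 0.0552 to 0.123). Cd101 was not called without young MCAo 1 or 2 or aged MCAo 4 (adjusted p 0.0607 to 0.0889). Eosinophil markers were not called without aged MCAo 2 (adjusted p = 0.0833). Mmp8, Fpr2, Cd101 and eosinophil markers were not called without aged MCAo 2 and 4 (adjusted p 0.0771 to 0.184). Gapdh and Cd101 were not called from the 8 libraries alone (adjusted p 0.0588 to 0.0613).

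The edgeR count of 182 was 45 (21 higher) without young MCAo 1, 65 (26) without young MCAo 2, 95 (45) without young MCAo 4, 193 (80) without aged MCAo 1, 177 (82) without aged MCAo 3 and 57 (27) without aged MCAo 4. It was 59 without aged MCAo 2 and 4, and 502 by DESeq2. The split was 203 higher and 219 lower without a filter on low counts, 276 and 143 by limma-voom and 99 and 46 from the 8 libraries alone. Of the lists, camera with the preset correlation called 16 of 33, 1 with an estimated correlation, and fry called 9. As many lists were called in 2 of 35 splits of the same libraries, the real one included.

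**Figure D3:**
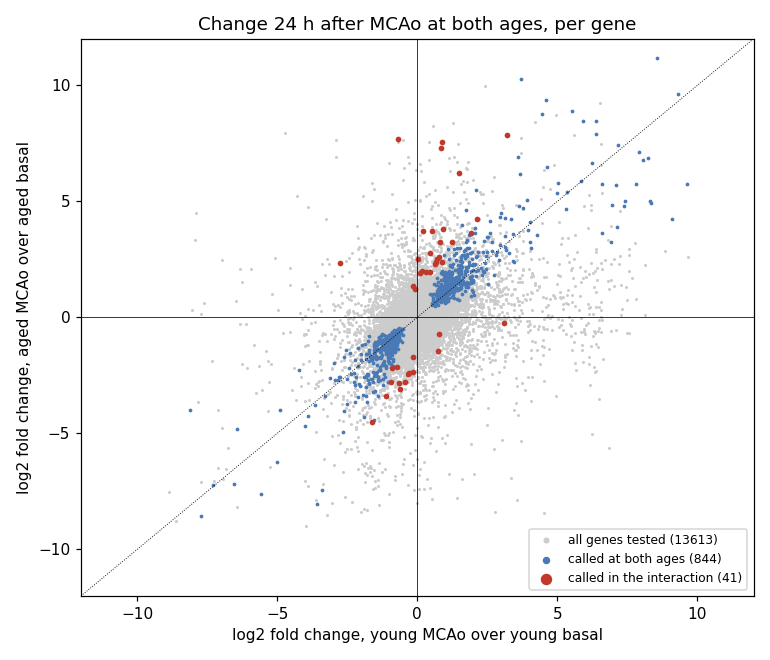
Log2 fold change after MCAo in young (x axis) against aged mice (y axis) for 13613 genes, where blue points passed the test at both ages (844), red points passed in the interaction (41) and the dotted line marks equal change. Cxcl3 and Ngp rose by log2 7.55 and 7.30 in aged mice.

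Whether the change after MCAo depends on age was tested by the interaction, which 41 genes passed, 26 with a higher and 15 with a lower value in aged mice. The chemokine gene Cxcl3 had the largest value among the genes named (log2 6.66, SE 0.95, adjusted p = 0.00670), with mean levels of 2.52 CPM in young basal, 4.81 in young MCAo, 0.548 in aged basal and 103 CPM in aged MCAo mice. Prok2 (log2 4.63, SE 0.72, adjusted p = 0.0107), Ifitm6 (log2 2.92, SE 0.48, adjusted p = 0.0160) and Cnnm2 (log2 2.45, SE 0.38, adjusted p = 0.0107) also had higher values in aged mice. So had Ngp (6.45), Thbs1 (3.50), which encodes thrombospondin-1, Serpinb1a (3.19) and the transglutaminase gene Tgm1 (2.47), while Fosb (-2.90) and Pigl (-2.46) had lower ones, with adjusted p from 0.0243 to 0.0494. None of Cxcr2 (0.55), Cxcr4 (-0.90), Ly6g (1.79), Itgam (0.38), S100a8 (0.54), Il1b (-0.81), Ltf (6.64) and Camp (5.50) passed. Ifitm6 was not called without aged basal 4 or young MCAo 1 (adjusted p 0.0567 to 0.0661). Ngp was not called on leaving out any library but young basal 3 or aged MCAo 1 or 3 (adjusted p 0.0726 to 0.160). Thbs1 was not called on leaving out any library but young MCAo 4 or aged MCAo 1 or 3 (adjusted p 0.0578 to 0.126). Serpinb1a was not called without young basal 4, aged basal 2, 3 or 4, young MCAo 1 or 2 or aged MCAo 4 (adjusted p 0.0524 to 0.0867). Tgm1 was not called on leaving out any library but young basal 2 or 3, aged basal 1, young MCAo 3 or aged MCAo 1 or 2 (adjusted p 0.0531 to 0.0867). Fosb was not called on leaving out any library but young MCAo 3 (adjusted p 0.0530 to 0.124). Pigl was not called on leaving out any library but young MCAo 3 or aged MCAo 1, 2 or 3 (adjusted p 0.0524 to 0.102). Cxcl3, Ngp, Thbs1, Serpinb1a and Fosb were not called by limma-voom (adjusted p 0.0846 to 0.383). Ngp was not called with a filter at a mean of 5 CPM (adjusted p = 0.0739). Ngp, Thbs1, Serpinb1a and Fosb were not called without aged MCAo 2 and 4 (adjusted p 0.0824 to 0.265). Cxcl3 (log2 5.82 without young basal 2), Prok2 (5.65 without aged basal 1) and Ngp (4.38 without aged MCAo 4) moved by over 1.5 times in fold.

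Of 17 specific granule genes, 6 had a higher interaction value, or 14 adjusted over the list alone (camera adjusted p = 7.23e-19, adjusted p = 0.0558 with an estimated correlation). These included Orm1 (log2 4.72), an acute-phase glycoprotein, and Ltb4r1 (1.85). The median of this list was 1.65, and 0.92 with 2 members passing without aged MCAo replicates 2 and 4, left out after the data were seen because they had the most Ngp, itself a gene of this list; aged MCAo 4 stood at a mean log2 CPM of 10.57 and the others of its group at 8.76 to 9.04. Beside it 12 B cell markers had a median of -1.91 (camera adjusted p = 0.00433, adjusted p = 0.159 with an estimated correlation), 13 monocyte and macrophage markers one of -1.41 (camera adjusted p = 0.0190, adjusted p = 0.197 with an estimated correlation) and 10 erythroid markers one of -1.14 (camera adjusted p = 0.00118, adjusted p = 0.424 with an estimated correlation). Of 12 genes raised in CXCR4-high neutrophils, 0 were higher and 1 lower, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.402), namely Itgax (-2.14), with a median of 0.16 and a mean of -0.15. Of 30 NF-kappaB target and cytokine genes, 1 was higher and 1 lower, or 2 and 3 adjusted over the list alone (camera adjusted p = 0.676), Cxcl3 and the inflammasome sensor Nlrp3 (-1.55). Of 7 azurophil granule and progenitor genes, 0 were higher and 1 lower, or 1 and 3 adjusted over the list alone (camera adjusted p = 0.0256, adjusted p = 0.159 with an estimated correlation), namely Clec12a (-2.35). No glycolysis or interferon-stimulated gene passed, at medians of 0.63 (camera adjusted p = 2.46e-06, adjusted p = 0.159 with an estimated correlation) and 0.78 (camera adjusted p = 8.99e-10, adjusted p = 0.284 with an estimated correlation). Orm1 was not called without aged basal 2 or 4, young MCAo 1, 2 or 4 or aged MCAo 4 (adjusted p 0.0524 to 0.0891). Ltb4r1 was not called without young basal 1 or 4, aged basal 3 or 4, young MCAo 1 or 2 or aged MCAo 4 (adjusted p 0.0513 to 0.0867). Monocyte and macrophage markers were not called without young basal 1, 2, 3 or 4, aged basal 2, young MCAo 1 or 3 or aged MCAo 1 or 4 (adjusted p 0.0648 to 0.170). Itgax was not called without young basal 1, 2 or 4, aged basal 3 or 4, young MCAo 1 or 2 or aged MCAo 4 (adjusted p 0.0558 to 0.0867). Nlrp3 was not called on leaving out any library but young basal 3, young MCAo 3 or aged MCAo 1, 2 or 3 (adjusted p 0.0548 to 0.103). Azurophil granule and progenitor genes were not called on leaving out any library but young MCAo 3 or aged MCAo 2 or 4 (adjusted p 0.0856 to 0.287). Orm1 and Itgax were not called by limma-voom (adjusted p 0.0688 to 0.0834). Orm1, Itgax and Nlrp3 were not called without aged MCAo 2 and 4 (adjusted p 0.0884 to 0.141).

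The interaction count of 41 was 19 (11 higher) without young basal 1, 25 (19) without young basal 2, 43 (22) without young basal 3, 12 (10) without young basal 4, 35 (27) without aged basal 1, 16 (11) without aged basal 2, 15 (10) without aged basal 3, 8 (6) without aged basal 4, 6 (5) without young MCAo 1, 9 (7) without young MCAo 2, 20 (13) without young MCAo 4, 49 (20) without aged MCAo 1, 67 (45) without aged MCAo 2, 35 (18) without aged MCAo 3 and 7 (6) without aged MCAo 4. The split was 133 higher and 154 lower without a filter on low counts and 16 and 5 without aged MCAo 2 and 4. The count was 259 by DESeq2. Of the lists, camera with the preset correlation called 14 of 33, 0 with an estimated correlation, and fry called 7. As many lists were called in 4 of 100 splits of the same libraries, the real one included.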

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

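Of the tests given here, those chosen only after the result was seen were those without aged MCAo replicates 2 and 4 and the comparison of B cell with platelet and other scores; the depth and length tests were set before. A library stood apart from the others of its group, by Dixon's test at the 95% level, in 35 of 536 groups of 4 values, where chance gives about 1 in 20, or 26.8. Aged MCAo replicates 4 (7) and 2 (6) had the most.

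Specific granule genes had a mean log2 CPM of 10.57 in aged MCAo 4 and 8.76 to 9.04 in the others. Ltf was 1332 in aged MCAo 4 and 2.32 to 53.6 CPM in the others. Camp was 309 in aged MCAo 4 and 1.11 to 17.5 CPM in the others. Dstn was 637 in aged MCAo 4 and 364 to 403 CPM in the others. Ngp was 14268 in aged MCAo 4 and 318 to 2379 CPM in the others. Egr1 was 22.8 in aged MCAo 4 and 6.06 to 7.18 CPM in the others. Orm1 was 20.6 in aged MCAo 4 and 5.87 to 8.31 CPM in the others. Gelatinase granule and secretory vesicle genes had a mean log2 CPM of 9.50 in aged MCAo 2 and 9.91 to 9.93 in the others. Lysosome and autophagy genes had a mean log2 CPM of 6.50 in aged MCAo 2 and 7.20 to 7.26 in the others. Eosinophil markers had a mean log2 CPM of -0.43 in aged MCAo 2 and 0.85 to 0.98 in the others. Cxcr4 was 19.9 in aged MCAo 2 and 25.4 to 26 CPM in the others. H2-Q6 was 83.9 in aged MCAo 2 and 7.26 to 8.47 CPM in the others. Bcl2l1 was 142 in aged MCAo 2 and 205 to 211 CPM in the others. The share of counts in the 10 most counted genes was 14.7% in young basal 4 and 13.8 to 13.9% in the others. NF-kappaB target and cytokine genes had a mean log2 CPM of 5.97 in young basal 4 and 6.39 to 6.41 in the others. Immediate-early and heat shock genes had a mean log2 CPM of 7.76 in young basal 4 and 8.35 to 8.41 in the others. S100a8 was 21155 in young basal 4 and 13368 to 14679.8 CPM in the others.

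Coagulation and fibrinolysis genes had a mean log2 CPM of 5.82 in young MCAo 2 and 5.39 to 5.45 in the others. Ltf was 99.1 in young MCAo 2 and 4.54 to 13.4 CPM in the others. Camp was 25.7 in young MCAo 2 and 0.365 to 3.49 CPM in the others. Ighm was 70.5 in young MCAo 2 and 124 to 125 CPM in the others. Cxcr4 was 82.2 in aged basal 1 and 66.8 to 69.3 CPM in the others. Fam169b was 2.29 in aged basal 1 and 0.0974 to 0.370 CPM in the others. Xiap was 67.1 in aged basal 1 and 44.8 to 47.7 CPM in the others. Detected genes numbered 25350 in aged basal 4 and 16633 to 17703 in the others. Lipg was 0.602 in aged basal 4 and 0 to 0.0685 CPM in the others. Cxcl3 was 5.86 in young basal 2 and 1.16 to 1.58 CPM in the others. Nos2 was 0.624 in young basal 2 and 0 to 0.0322 CPM in the others. Chil3 was 3537 in young MCAo 3 and 626 to 1108 CPM in the others. Cxcl10 was 0 in young MCAo 3 and 0.469 to 0.561 CPM in the others. Fam169b was 0.0322 in young basal 3 and 0 CPM in the others. Lrrc75b was 0.535 in young basal 1 and 0 CPM in the others. Bst2 was 4.20 in aged basal 3 and 8.28 to 9.07 CPM in the others. Atp5e was 15.7 in aged MCAo 3 and 47.7 to 51.3 CPM in the others. Hgh1 was 1.67 in aged MCAo 1 and 0 CPM in the others.

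The change after MCAo differed with age in the edgeR interaction test for 18 of the genes that the text names. Their log2 interaction values were above 0 for Cxcl3 (6.66), Ifitm6 (2.92), Prok2 (4.63), Serpinb1a (3.19), Dstn (1.65), Ltb4r1 (1.85), Ngp (6.45), Thbs1 (3.50), Cnnm2 (2.45), Tgm1 (2.47) and Orm1 (4.72). They were below 0 for Fosb (-2.90), Anxa6 (-2.09), Itgax (-2.14), Plekhm3 (-2.16), Clec12a (-2.35), Pigl (-2.46) and Nlrp3 (-1.55). Camera gave a difference for 14 lists, among them medians of -0.63 for azurophil granule and progenitor genes, 1.65 for specific granule genes, 0.39 for gelatinase granule and secretory vesicle genes, 0.42 for mature neutrophil genes and 0.48 for NADPH oxidase genes. Further medians were 0.15 for nuclear oxidative phosphorylation genes, 0.56 for mitochondrially encoded protein genes, 0.63 for glycolysis genes, 0.78 for interferon-stimulated genes and 0.34 for lysosome and autophagy genes. The last medians were 0.31 for coagulation and fibrinolysis genes, -1.91 for B cell markers, -1.41 for monocyte and macrophage markers and -1.14 for erythroid markers. With an estimated correlation between genes, 0 lists were called. Ifitm6 was not called without aged basal 4 or young MCAo 1 (adjusted p 0.0567 to 0.0661). Serpinb1a was not called without young basal 4, aged basal 2, 3 or 4, young MCAo 1 or 2 or aged MCAo 4 (adjusted p 0.0524 to 0.0867). Fosb was not called on leaving out any library but young MCAo 3 (adjusted p 0.0530 to 0.124). Itgax was not called without young basal 1, 2 or 4, aged basal 3 or 4, young MCAo 1 or 2 or aged MCAo 4 (adjusted p 0.0558 to 0.0867). Ltb4r1 was not called without young basal 1 or 4, aged basal 3 or 4, young MCAo 1 or 2 or aged MCAo 4 (adjusted p 0.0513 to 0.0867). Ngp was not called on leaving out any library but young basal 3 or aged MCAo 1 or 3 (adjusted p 0.0726 to 0.160). Thbs1 was not called on leaving out any library but young MCAo 4 or aged MCAo 1 or 3 (adjusted p 0.0578 to 0.126). Tgm1 was not called on leaving out any library but young basal 2 or 3, aged basal 1, young MCAo 3 or aged MCAo 1 or 2 (adjusted p 0.0531 to 0.0867). Pigl was not called on leaving out any library but young MCAo 3 or aged MCAo 1, 2 or 3 (adjusted p 0.0524 to 0.102). Orm1 was not called without aged basal 2 or 4, young MCAo 1, 2 or 4 or aged MCAo 4 (adjusted p 0.0524 to 0.0891). Nlrp3 was not called on leaving out any library but young basal 3, young MCAo 3 or aged MCAo 1, 2 or 3 (adjusted p 0.0548 to 0.103). Azurophil granule and progenitor genes were not called on leaving out any library but young MCAo 3 or aged MCAo 2 or 4 (adjusted p 0.0856 to 0.287). Nuclear oxidative phosphorylation genes were not called without young basal 1 or 2, aged basal 1, young MCAo 1, 3 or 4 or aged MCAo 4 (adjusted p 0.0550 to 0.975). Mitochondrially encoded protein genes were not called without young basal 2 or 4, aged basal 1 or 3, young MCAo 1, 3 or 4 or aged MCAo 4 (adjusted p 0.0501 to 0.255). Monocyte and macrophage markers were not called without young basal 1, 2, 3 or 4, aged basal 2, young MCAo 1 or 3 or aged MCAo 1 or 4 (adjusted p 0.0648 to 0.170). Cxcl3, Serpinb1a, Fosb, Itgax, Ngp, Thbs1 and Orm1 were not called by limma-voom (adjusted p 0.0688 to 0.383). Serpinb1a, Fosb, Itgax, Ngp, Thbs1, Orm1, Nlrp3, nuclear oxidative phosphorylation genes and mitochondrially encoded protein genes were not called without aged MCAo 2 and 4 (adjusted p 0.0824 to 0.320). Ngp was not called with a filter at a mean of 5 CPM (adjusted p = 0.0739). Cxcl3 (log2 5.82 without young basal 2), Prok2 (5.65 without aged basal 1) and Ngp (4.38 without aged MCAo 4) moved by over 1.5 times in fold.

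Specific granule genes had a median log2 interaction of 1.65 over 17 genes, 16 of them above 0 and 6 passing (camera adjusted p = 7.23e-19, adjusted p = 0.0558 with an estimated correlation). Thinning every library to the smallest total of 9709452 counts left the median at 1.68, which argues against depth as the cause. Without aged MCAo replicates 2 and 4 the median was 0.92, between the bounds set for that test, with 15 genes above 0 and 2 passing, so these libraries may carry part of the difference. They were left out for having the most Ngp of their group, and Ngp is itself in the list, so part of that drop follows from the choice and the test leaves the question open. The sample names of both libraries also carry a letter B, as does that of young MCAo 3. Whether it marks a difference in collection or preparation is not known. The interaction tests a difference with age, not its cause: age itself and the maturity of the circulating cells stay open as hypotheses, which the medians of mature neutrophil genes (0.42, adjusted p = 0.416 with an estimated correlation) and azurophil granule and progenitor genes (-0.63, adjusted p = 0.159 with an estimated correlation) do not settle.

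After MCAo ribosomal protein genes had a median of -0.86 in young (camera adjusted p = 2.87e-36, adjusted p = 0.10 with an estimated correlation). In aged mice it was -0.85 (camera adjusted p = 4.82e-18, adjusted p = 0.229 with an estimated correlation). Not every gene passed. Genes outside the list matched on exonic length and level (318 genes) had medians of -0.37 (SE 0.0299) and -0.22 (SE 0.0424). Both lie between the bounds set, but length and level were matched together, so length stays open as a cause. Fewer reads from lymphocytes, which are rich in these transcripts, and a response of the neutrophils to stroke or surgery also stay open and were not tested.

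Of 12 B cell markers 4 fell in young (camera adjusted p = 2.31e-06, adjusted p = 0.0566 with an estimated correlation) and 9 in aged mice (camera adjusted p = 1.44e-08, adjusted p = 0.0102 with an estimated correlation) after MCAo, although a neutrophil gate would remove such cells. The most abundant of the list were Ighm, at 389.6 ± 33.3 and 365 ± 23 CPM before and 111 ± 27.0 and 29.4 ± 16.4 CPM after MCAo in young and aged mice, and Bank1, at 39.9 ± 15.7 and 28.8 ± 5.91 CPM before and 10.4 ± 4.02 and 2.80 ± 0.698 CPM after (SD, n = 4). The B cell score fell more than the platelet score, by differences of -1.78 (SE 0.72) in young and -3.48 (SE 0.42) in aged mice. The platelet list was picked after its median was seen to lie far from the B cell one. The B cell score was then set against 7 other lists, with SEs that ignore the shared libraries. It fell more by over 2 SE than 6 of them in young mice, erythroid markers excepted, and 7 in aged mice. T and dendritic cell scores were low before MCAo (-1.05 to 0.99), so they had less room to fall. Neutrophils may express genes of these lists, so a lower share of all other cells alike stays open. A lower share of B cells, in blood or in the sorted fraction, and an effect of stroke or age on them stay open and untested.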

How the results depend on the processing

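Leaving out aged MCAo replicates 2 and 4 together, DESeq2 size factors for the lists and the permutation tests of the replicate numbers were chosen after the data were seen; the other settings were not. Counts of genes that moved by over 1.5 times are given here against the reported counts of 1 (age, untreated), 182 (age after MCAo), 1208 (MCAo in young), 2480 (MCAo in aged) and 41 (interaction), and the cause was not tested. The DESeq2 test gave 157, 502, 1910 and 259 for all but MCAo in aged mice. No filter on low counts gave 166, 422 and 287, and a filter at a mean of 5 CPM gave 3, 307 and 74, for age in untreated mice, age after MCAo and the interaction. For age in untreated mice limma-voom gave 0, DESeq2 size factors 0 and the 8 libraries alone 0, and limma-voom gave 419 for age after MCAo. Without aged MCAo replicates 2 and 4 the counts were 0, 59, 1535 and 21 for all but MCAo in young mice.

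Leaving out 1 library at a time gave 0 to 5 genes for age in untreated mice, 45 to 193 for age after MCAo, 627 to 1495 for MCAo in young, 1834 to 2595 for MCAo in aged and 6 to 67 for the interaction, and 3 to 9, 14 to 20, 14 to 19, 16 to 21 and 10 to 17 lists in the same order. The correlation of the MCAo changes at both ages was 0.430, and 0.742 over genes of at least 5 CPM. With 1 library left out and 14060 to 14409 genes kept it was 0.339 to 0.410, so library and gene set are not separated. For the age differences it was -0.00898 to 0.0398. Against reported counts of 8, 16, 17, 17 and 14 lists, an estimated correlation between genes gave 0, 1, 0, 3 and 0, and fry gave 0, 9 and 7 for age in untreated mice, age after MCAo and the interaction. The camera direction of nuclear oxidative phosphorylation genes in the interaction reversed without aged MCAo replicate 4 (adjusted p = 0.975, and 7.81e-05 to 0.975 over single libraries left out) and without replicates 2 and 4 (adjusted p = 0.320); the cause was not tested.

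Without a filter the median log2 of all genes shifted to 0.22 for age in untreated mice, -0.47 for MCAo in aged and -0.52 for the interaction, limma-voom shifted it to 0.17 for MCAo in young and -0.13 for the interaction, and leaving out aged MCAo replicates 2 and 4 shifted it to -0.11, -0.16 and -0.16 for age after MCAo, MCAo in aged and the interaction. Deviations from the group means had correlations of -0.0447 to 0.226 between same-numbered libraries, 1 of 24 over 0.1, so the numbers were not taken as pairing. Their mean was 0.0248, against -0.00815 for different numbers (permutation p = 0.0142), and 8 of 16 libraries correlated best with their own number, where shuffled numbers gave 3.99 (permutation p = 0.0718). These 1-sided tests over 100000 shuffles are a hint from the data, not the design, that some numbers are shared in more than name, and the sample name of aged basal replicate 3 carries the number 4. A replicate block gave 0, 177, 1248, 2463 and 38 genes and 8, 15, 17, 18 and 14 lists. Of the reported genes, 0 of 1, 148 of 182, 1081 of 1208, 2271 of 2480 and 28 of 41 were shared. Of those named in the text, the ones not called with the block were hypoxia genes, Bax, Fam169b, Ptgs2 and Nlrp3 for age after MCAo; Hjurp for age in untreated mice; Hba-a1 for MCAo in young; Ngp, Thbs1, Fosb, Itgax and Nlrp3 for the interaction (adjusted p 0.0503 to 0.0927). Leaving out aged basal replicate 3 or replicate 4, which may be 1 sample, gave 1 or 0 genes for age in untreated mice, 1834 or 1876 for MCAo in aged and 15 or 8 for the interaction. Depth limits genes of few counts most, since the smallest library held 9709452 counts.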

Other observations

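The lists and splits given here were set before the results were seen; leaving out aged MCAo 2 and 4 was not. Genes that regulate apoptosis moved both ways in aged mice after MCAo. Of 22 apoptosis regulators, 5 rose and 7 fell, or 7 and 8 adjusted over the list alone (camera adjusted p = 0.451), with the survival genes Bcl2l1 (log2 2.05, SE 0.26, adjusted p = 2.58e-05) and Xiap (1.15, SE 0.18, adjusted p = 2.24e-04) among the rises and the pore-forming Bax (-2.57, SE 0.32, adjusted p = 2.33e-05) among the falls. In young mice Bax fell too (-1.16), and none of the 3 passed the interaction (Bcl2l1 1.37, Xiap 0.96, Bax -1.41). Of 16 coagulation and fibrinolysis genes, 4 rose and 1 fell, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.0872), with Thbs1 (3.70) and Alox5ap (1.19), which activates leukotriene synthesis, among the rises. After MCAo Alox5ap was higher in aged than in young mice (0.76). Of 7 mitochondrially encoded protein genes, 5 rose, or 6 adjusted over the list alone (camera adjusted p = 4.57e-04, adjusted p = 0.240 with an estimated correlation), with mt-Co1 at 1.78, and 6 more of this list, with mt-Co2 and mt-Co3 at 0 counts in every library, were not tested. The nuclear genes of the same respiratory complexes had a median of -0.37. In young mice the medians of the mitochondrially encoded and the nuclear genes were 0.61 (camera adjusted p = 0.0246, adjusted p = 0.465 with an estimated correlation) and -0.60. Bax in the young comparison was not called without young basal 1 or 2 or young MCAo 3 or 4 (adjusted p 0.0508 to 0.0898). Alox5ap in the comparison of ages after MCAo was not called without young MCAo 1, 2 or 4 or aged MCAo 4 (adjusted p 0.0580 to 0.0851). Mitochondrially encoded protein genes in the young comparison were not called without young basal 1 or 3 or young MCAo 2 (adjusted p 0.0569 to 0.0923). Bax in the young comparison was not called from the 8 libraries alone (adjusted p = 0.0506). Alox5ap in the comparison of ages after MCAo was not called without aged MCAo 2 and 4 (adjusted p = 0.0643) or from the 8 libraries alone (adjusted p = 0.0588).

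Lists not described above had these median log2 values, with camera tests, after MCAo. Antioxidant genes were at -0.38 (adjusted p = 0.00564, adjusted p = 0.170 with an estimated correlation) in young and -0.15 (adjusted p = 0.0872) in aged mice. Unfolded protein response genes were at -0.51 (adjusted p = 0.00287, adjusted p = 0.210 with an estimated correlation) in young and -0.54 (adjusted p = 0.0828) in aged mice. Hypoxia genes were at -0.44 (adjusted p = 0.0213, adjusted p = 0.191 with an estimated correlation) in young and -0.12 (adjusted p = 0.333) in aged mice. Lysosome and autophagy genes were at -0.24 (adjusted p = 0.0213, adjusted p = 0.506 with an estimated correlation) in young and 0.28 (adjusted p = 0.496) in aged mice. NADPH oxidase genes were at -0.12 (adjusted p = 0.278) in young and 0.32 (adjusted p = 0.299) in aged mice. Phagocytic receptor and signalling genes were at 0.06 (adjusted p = 0.683) in young and 0.22 (adjusted p = 0.189) in aged mice. Adhesion and chemotaxis receptors were at 0.10 (adjusted p = 0.775) in young and 0.26 (adjusted p = 0.365) in aged mice. Cell cycle genes were at 0.09 (adjusted p = 0.770) in young and -0.85 (adjusted p = 0.278) in aged mice. In young mice the apoptosis regulators were at -0.05 (adjusted p = 0.278) and the coagulation and fibrinolysis genes were at 0.03 (adjusted p = 0.593). Genes raised in CXCR4-high neutrophils were at 0.10 (adjusted p = 0.480) in young mice. Hypoxia genes in the young comparison were not called without young basal 3 (adjusted p = 0.0570). Lysosome and autophagy genes in the young comparison were not called without young MCAo 2 (adjusted p = 0.108).

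Of 7 azurophil granule and progenitor genes, 0 rose, or 0 adjusted over the list alone (camera adjusted p = 0.163), with a median of -0.54 in young mice after MCAo. Of 7 azurophil granule and progenitor genes, 1 rose and 2 fell, or 1 and 4 adjusted over the list alone (camera adjusted p = 0.00477, adjusted p = 0.0944 with an estimated correlation), with a median of -0.92 in aged mice. Of 21 glycolysis genes, 1 rose and 4 fell, or 4 and 6 adjusted over the list alone (camera adjusted p = 0.0527), with a median of -0.39 in young mice. Of 21 glycolysis genes, 6 rose and 2 fell, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0504), with a median of 0.21 in aged mice.

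Markers of other cells had these median log2 values, with camera tests, after MCAo. Monocyte and macrophage markers were at -0.03 (adjusted p = 0.775) in young and -2.04 (adjusted p = 0.0477, adjusted p = 0.229 with an estimated correlation) in aged mice. T cell markers were at -0.76 (adjusted p = 0.683) in young and -0.84 (adjusted p = 0.509) in aged mice. Dendritic cell markers were at -1.45 (adjusted p = 0.593) in young and -1.04 (adjusted p = 0.365) in aged mice. Plasma cell markers were at 0.11 (adjusted p = 0.836) in young and -1.12 (adjusted p = 0.882) in aged mice. Platelet markers were at -0.37 (adjusted p = 0.228) in young and -0.26 (adjusted p = 0.409) in aged mice. Eosinophil markers in young mice were at -1.07 (adjusted p = 0.12). Monocyte and macrophage markers in the aged comparison were not called on leaving out any library but aged basal 1 or 3 or aged MCAo 2 (adjusted p 0.0507 to 0.107). Nor were they called without aged MCAo 2 and 4 (adjusted p = 0.0959).

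Camera also called 4 lists between untreated aged and young mice, with these median log2 values. The specific granule genes were at -0.29 (adjusted p = 0.0375, adjusted p = 0.898 with an estimated correlation). The nuclear oxidative phosphorylation genes were at -0.13 (adjusted p = 0.0375, adjusted p = 0.981 with an estimated correlation). The unfolded protein response genes were at -0.18 (adjusted p = 0.0318, adjusted p = 0.873 with an estimated correlation). The lysosome and autophagy genes were at -0.12 (adjusted p = 0.0318, adjusted p = 0.898 with an estimated correlation). Specific granule genes were not called without young basal 1, 2 or 4 or aged basal 3 or 4 (adjusted p 0.0528 to 0.325). Nuclear oxidative phosphorylation genes were not called without young basal 1, 2 or 4 or aged basal 1 (adjusted p 0.0513 to 0.700). Unfolded protein response genes were not called without young basal 3 or 4 or aged basal 1 or 4 (adjusted p 0.0513 to 0.121). Lysosome and autophagy genes were not called without young basal 2, 3 or 4 or aged basal 1, 3 or 4 (adjusted p 0.0506 to 0.141).

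For age after MCAo, camera called further lists, with these median log2 values. Mature neutrophil genes were at 0.39 (adjusted p = 2.67e-06, adjusted p = 0.141 with an estimated correlation). Mitochondrially encoded protein genes were at 0.71 (adjusted p = 3.63e-05, adjusted p = 0.141 with an estimated correlation). Coagulation and fibrinolysis genes were at 0.27 (adjusted p = 1.51e-04, adjusted p = 0.0570 with an estimated correlation). NADPH oxidase genes were at 0.32 (adjusted p = 0.00361, adjusted p = 0.0966 with an estimated correlation). Hypoxia genes were at 0.07 (adjusted p = 0.0381, adjusted p = 0.195 with an estimated correlation). Lysosome and autophagy genes were at 0.16 (adjusted p = 0.0347, adjusted p = 0.597 with an estimated correlation). Cytosolic ribosomal protein genes were at -0.23 (adjusted p = 0.00296, adjusted p = 0.655 with an estimated correlation). Cell cycle genes were at -0.66 (adjusted p = 0.0347, adjusted p = 0.141 with an estimated correlation). Hypoxia genes were not called without young MCAo 1, 2 or 4 or aged MCAo 1, 3 or 4 (adjusted p 0.0608 to 0.0799). Lysosome and autophagy genes were not called without young MCAo 2 or 4 or aged MCAo 1, 3 or 4 (adjusted p 0.0902 to 0.346). Cytosolic ribosomal protein genes were not called without young MCAo 2 or aged MCAo 3 (adjusted p 0.738 to 0.767).

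The median, the mean and the camera direction of a list differed in sign in these cases. For age in untreated mice they were the genes raised in CXCR4-high neutrophils, antioxidant genes, glycolysis genes, phagocytic receptor and signalling genes, coagulation and fibrinolysis genes, cell cycle genes, MHC class I presentation genes and eosinophil markers. For age after MCAo they were the genes raised in CXCR4-high neutrophils, NF-kappaB target and cytokine genes, glucocorticoid-induced genes, apoptosis regulators and dendritic cell markers. For MCAo in young they were the hypoxia genes, coagulation and fibrinolysis genes and plasma cell markers. For MCAo in aged they were the genes raised in CXCR4-high neutrophils and plasma cell markers. For the interaction they were the genes raised in CXCR4-high neutrophils, adhesion and chemotaxis receptors, antioxidant genes, hypoxia genes, glucocorticoid-induced genes, apoptosis regulators, plasma cell markers and platelet markers.

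Splits of the same libraries into other groups of the same sizes, the real one included, test chance among libraries, not animals. For genes chance can be excluded for age after MCAo (182 against 1 at most in other splits, 1 of 35 as large). So it can for MCAo in young (1208 against 1, 1 of 35) and aged (2480 against 0, 1 of 35). The interaction (41 against 10, 1 of 100 drawn) stays open. Splits can undo the age difference that 33 of its genes had after MCAo. Chance cannot be excluded for age in untreated mice (1 against 1, 4 of 35). For counts of called lists the real split was highest for MCAo in young (17 against 16, 1 of 35). The interaction gave 14 against 17, 4 of 100 being as large. With 1 library left out the counts fell to 14 for MCAo in young (young basal 3) and 10 for the interaction (young MCAo 1). These lay below the 16 and 17 reached by other splits of all libraries. Both counts were 0 with an estimated correlation. The shares of 1 of 35 and 4 of 100 lie under the 0.05 set beforehand. Given these counts, chance is still not taken as excluded for either. For lists chance cannot be excluded for age in untreated mice (8 against 8, 2 of 35). Nor can it for age after MCAo (16 against 17, 2 of 35) or MCAo in aged (17 against 18, 3 of 35).

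Aged basal replicate 4 held 3741 genes detected in no other library, at a total of 16729496 counts.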
